A study of Mus musculus with 12 samples.

How the data were processed

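Bulk RNA was sequenced from subcutaneous tumours that YUMM2.1 mouse melanoma cells formed in immunocompetent C57BL/6J mice, per the labels' protocols. Mice received isotype control IgG, an antibody to B7-H3, an antibody to PD1, or both antibodies, starting when tumours measured 20 to 50 mm3, and each of the 4 groups has 3 samples. Per the labels' protocols, total RNA with an integrity number of 7.0 or more and at least 500 ng was depleted of ribosomal RNA and made into libraries with an Illumina TruSeq total RNA kit. Per the submitters' processing notes, FastQC 0.11.8 was run and the genome build was GRCm38. The program that assigned reads to transcripts is not given in the sources used here, nor is its setting for strand.

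Each deposited file lists transcripts with a length, an effective length, a TPM value and an estimated count of reads, per the file headers. The estimated counts that the authors deposited are not scaled, and they were the values tested. TPM values were not used here, because a share of all transcripts moves with the few sequences that take most reads. The files hold 58083 transcripts, and 87.3% of their lengths are multiples of 3, so the lengths are coding lengths. Transcript identifiers were matched to the GENCODE annotation of GRCm38, 57169 with the same version and 57473 with any version. The other 610 (1.05%) stayed unmatched and took 0.105% ± 0.0341 (SD, n = 3) of reads in isotype control, 0.408% ± 0.00628 in anti-B7-H3, 0.194% ± 0.0359 in anti-PD1 and 0.277% ± 0.0104 in combination libraries. Of reads outside 12 satellite-like genes, which take most reads in isotype control libraries, the unmatched were 1.37% ± 0.113, 0.408% ± 0.00653, 0.684% ± 0.0559 and 0.403% ± 0.00514 in the same order, so isotype control loses the largest share on this scale. Estimated counts were summed per gene over 22195 genes and rounded. Genes whose near-identical copies share reads (class I heavy chains, immunoglobulin and T cell receptor constant genes, globins, guanylate-binding proteins, chemoreceptors) carry an added uncertainty, since the sharing of such reads is not described.

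Library totals ran from 3593110 to 21298142 reads. The precision of each value follows from its reads, so reads summed over the 3 libraries of a group are given beside genes of interest. Intervals and floors cover counting error only. Expected background was estimated from 1545 olfactory, vomeronasal and bitter taste receptor genes (chemoreceptor genes), whose transcription is not expected in tumours. Their reads per kilobase of coding length in a library, multiplied by a gene's coding length, gave the expected background reads of that gene.

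Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust spread, TMM scaling, filtering by expression, 1 mean per group, all 12 libraries in 1 fit). The filter left 13478 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 5 comparisons were each treatment against isotype control and the combination against each antibody alone, and the interaction asked whether the effect of both antibodies differs from the sum of the log2 effects of each. An adjusted p of a gene comes from this edgeR fit unless another setting is named with it. A set of 43 gene lists with 538 entries was tested with camera of limma 3.58.1 on log2 CPM (counts per library scaled to a common total) with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation. Values given for lists are medians of log2 fold changes over members tested, with camera's adjusted p over the lists, and 26 of the lists are described. Camera called 19, 17, 17, 30, 23 and 20 lists for anti-B7-H3, anti-PD1 and combination against isotype control, combination against anti-B7-H3, combination against anti-PD1 and the interaction. With an estimated correlation the counts were 12, 0, 6, 23, 15 and 9. The lists, tests, comparisons, naming rule and most alternatives were set before the data were examined.

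Genes named belong to 3 classes. The first is the antibody targets, their ligands and the other genes of the series title (Cd276, Pdcd1, Cd274, Pdcd1lg2, Cd47, Sirpa, Ctnnb1). The others are the 5 called genes with the largest positive and the 5 with the largest negative log2 fold change per comparison (mean of at least 1 CPM, no overlap between groups, no predicted or clone names), and up to 2 called members per direction of each list described. Part of the genes that the rule gives are named. Where a group had 0 reads of a gene, a fold is a lower bound against a floor of 3 reads over the group, and with 1 to 3 reads a ratio is given with its 95% interval.

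Alternatives were DESeq2 1.42.0 size factors, its Wald test, no filter on low counts, only the groups compared, a replicate block, an effective-length offset, mitochondrially encoded genes left out, calls of at least 2-fold, a spread that is not robust, an estimated correlation and fry for lists, and each library left out in turn. Another 3 were chosen after seeing the data. They keep only the genes well above background (expected background under 10% of their reads over all libraries, 8130 genes tested), subtract the expected background from each count, or leave out 12 satellite-like genes. Dropping the filter moved the median log2 fold change of all genes to -0.78, -0.48, -0.70 and -0.28 for anti-B7-H3, anti-PD1 and combination against isotype control and combination against anti-PD1, and to 0.46 for the interaction. Subtracting background moved it to 0.69, 0.52 and 0.67 in the comparisons with isotype control, to 0.10 for combination against anti-PD1 and to -0.55 for the interaction. It can overcorrect genes near background.

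The edgeR step was tested on simulated counts with 200 genes changed and a coefficient of variation of 0.056. For anti-B7-H3 against isotype control it recovered 53.7% of genes changed 1.5-fold, 86.6% changed 2-fold and 100% changed 4-fold (14605 genes tested), and 2.21% of calls were false. For anti-PD1 against isotype control it recovered 53.7%, 83.6% and 100% (14650 genes, 1.67% false), and for combination against isotype control 49.3%, 85.1% and 100% (14520 genes, 6.42% false). For the interaction it recovered 28.4% to 37.3%, 73.1% to 80.6% and 98.5% to 100%, with 1.26% to 7.74% false. Up to 8641 genes were called here, and simulated groups did not differ in background or satellite-like reads, so these rates may not apply. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.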

Results

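RNA of whole tumours of the mouse melanoma line YUMM2.1 was sequenced. The 12 libraries fall into 4 groups of 3: isotype control IgG, anti-B7-H3 (against the checkpoint protein of Cd276), anti-PD1 (against the T cell checkpoint receptor of Pdcd1) and the combination. The series set out to compare the immune cells within tumours of the 4 groups. Total reads per library were 15585622 to 21298142 in isotype control, 3593110 to 3937727 in anti-B7-H3, 8099713 to 10527704 in anti-PD1 and 4409772 to 5014931 in combination libraries. Within a group, median chi-squares between libraries lay little above counting noise (0.455). They were 0.636 to 0.734 in isotype control, 0.539 to 0.561 in anti-B7-H3, 0.621 to 0.633 in anti-PD1 and 0.549 to 0.58 in combination. The 54 pairs of libraries from different groups gave 2.07 to 6. Means within groups were 2.03 to 4.39, 1.36 to 1.45, 1.73 to 1.89 and 1.41 to 1.5 in that order, so some genes varied more. The p-values compare libraries, and the labels do not say whether each library came from its own mouse.

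A group of 12 satellite-like genes, which hold repeated sequence on chromosomes 9, 2 and 14, took 92.5% ± 1.93 (SD, n = 3) of matched reads in isotype control libraries, 72.0% ± 2.99 in anti-PD1, 31.4% ± 2.22 in combination and 0.145% ± 0.0679 in anti-B7-H3 libraries. Chemoreceptor genes, which serve smell and taste, moved in the same order. They held 7.32 ± 0.504 reads per kilobase of coding sequence in isotype control, 5.25 ± 0.223 in anti-PD1, 0.696 ± 0.066 in combination and 0.0915 ± 0.00684 in anti-B7-H3 libraries. Reads left for other genes ran from 1340782 to 1512937 in isotype control and from 3570258 to 3918163 in anti-B7-H3 libraries. Background at the chemoreceptor rate made up 18.6% ± 0.44 of these in isotype control, 7.05% ± 0.482 in anti-PD1, 0.787% ± 0.0134 in combination and 0.088% ± 0.0106 in anti-B7-H3 libraries. Lists of genes with few reads lie at that background in isotype control libraries: T cell genes held 153.7 ± 21.6 reads per library against 163 from background alone, natural killer cell genes 109.7 ± 15.1 against 108, and cytotoxic effector genes 52.0 ± 7.00 against 54.7. B cell genes held 187 ± 14.5 against 155, keratinocyte genes 257.1 ± 29.6 against 219, dendritic cell genes 283.7 ± 20.7 against 213, skeletal muscle genes 1596 ± 283 against 1140, type I interferon response genes 365.1 ± 59.5 against 246 and pigment genes 395.5 ± 63.9 against 176. Macrophage genes stood above it, with 1117 ± 130 reads against 197. Reads beyond background are given per 1e6 of the library total after TMM scaling over the genes well above background.

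**Figure D1:**
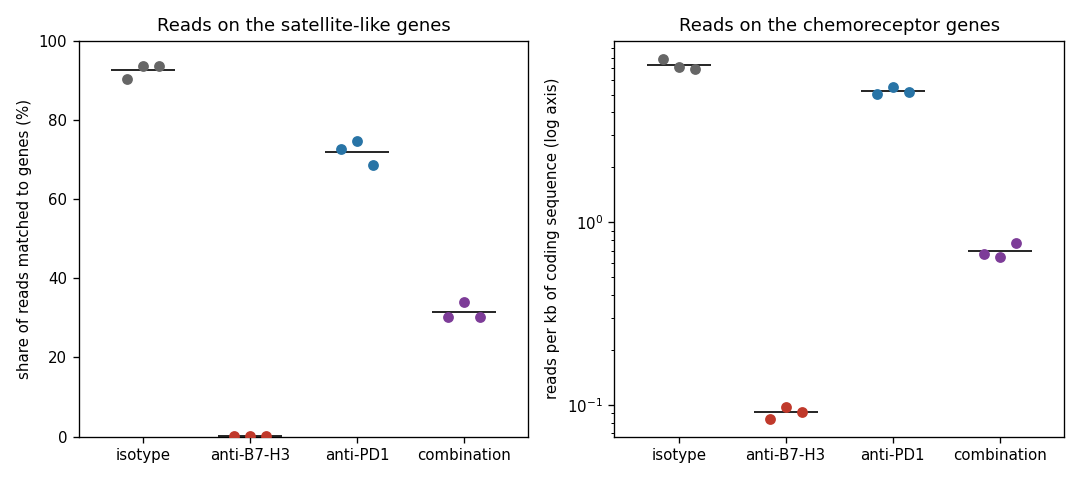
Share of matched reads in 12 satellite-like genes (percent, left) and reads per kilobase of chemoreceptor coding sequence (log axis, right) in each library, with lines at group means. Isotype control libraries sit at 90.28% to 93.7% and anti-B7-H3 libraries at 0.0944% to 0.222% of matched reads.

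Anti-B7-H3 was compared with isotype control (n = 3 each) to ask what blocking B7-H3 alone did to the tumour and its immune cells. Macrophage genes rose: all 16 tested members were called higher (16 adjusted over the list alone), with a median log2 fold change of 2.71 (adjusted p = 1.35e-09). Counts adjusted over the list alone equal those over all genes tested unless given beside them. Mrc1, the mannose receptor of macrophages, rose by 3.41 ± 0.0628 (log2 fold change ± SE), from 541 reads over the isotype control libraries to 25801. C1qc, a chain of complement C1q, rose by 3.26 ± 0.0732. Alternatively activated macrophage genes rose as well, 10 of 10 members, median 3.23 (adjusted p = 1.53e-07). The chitinase-like Chil3 rose by 4.24 and the lectin Mgl2 by 3.77. Of 6 monocyte genes 5 were higher (5 higher and 1 lower adjusted over the list alone), median 3.27, or 3.30 with genes of few reads at the floor (adjusted p = 0.00647, and adjusted p = 0.0665 with an estimated correlation). Ly6c2, a surface antigen of inflammatory monocytes, had 1 read in isotype control and 247 in anti-B7-H3 libraries, a ratio of 54.8 (1 read allows 9.74 to 2170). Complement genes were higher in 12 of 12, median 1.95 (adjusted p = 4.33e-07). C3 rose by 5.21 ± 0.0702 and properdin, Cfp, by 3.34. Chemokine genes were higher in 11 and lower in 2 of 16, median 1.92, or 1.69 with the floor (adjusted p = 0.00647, and 0.0874 with background subtracted). The monocyte attractant Ccl8 rose by 5.26, and Ccl9 by 4.01 (4.65 without isotype control replicate 1).

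Antigen presentation and interferon gamma response genes rose too. MHC class I presentation genes were higher in 14 of 14, median 2.92 (adjusted p = 2.77e-08). The heavy chain gene H2-K1 rose by 4.19 ± 0.0779 and H2-D1 by 3.76 ± 0.0675. MHC class II presentation genes were higher in 9 of 11, median 3.31 (adjusted p = 1.4e-05, and adjusted p = 0.0752 with an estimated correlation). H2-Aa rose by 3.85 and H2-Eb1 by 3.88. Interferon gamma response genes were higher in 16 and lower in 1 of 17, median 2.14 (adjusted p = 6.52e-06). The GTPase gene Gbp6 rose by 5.03 (5.75 without isotype control replicate 3) and the transcription factor Irf1 by 3.08. Gbp5, a related GTPase, fell by 5.05, from 5410 reads to 738. Its reads (3704 in anti-PD1, 1040 in combination) follow the order of satellite-like reads, and a link was not tested. Type I interferon response genes went both ways (8 higher and 8 lower of 22, median 0.07, mean -0.07, upward test, adjusted p = 0.802). B7 family ligands and Cd47 were higher in 7 of 9, median 1.73 (adjusted p = 0.00341).

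Among the antibody targets and their partners, Cd276 (chromosome 9, 58524298 to 58555437, GRCm38) rose by 0.56 ± 0.177 (adjusted p = 0.00492, 86 reads in isotype control and 569 in anti-B7-H3 libraries). That call was lost without isotype control replicate 2 (0.36, adjusted p = 0.0999), without isotype control replicate 3 (0.41, adjusted p = 0.0766) and over genes well above background (0.23, adjusted p = 0.28). Pdcd1 (chromosome 1, 94038305 to 94052553) stood at 0.69 ± 0.591 and did not pass (adjusted p = 0.313, 7 and 51 reads). The PD1 ligand genes Cd274 (chromosome 19, 29367455 to 29388095) and Pdcd1lg2 (chromosome 19, 29410919 to 29471161) rose by 1.80 ± 0.232 and 2.97 ± 0.214. Cd47, whose protein signals against phagocytosis, and Sirpa, the gene of its receptor on macrophages, rose by 1.78 ± 0.113 and 2.83 ± 0.104. Ctnnb1, which encodes beta-catenin, rose by 0.74 ± 0.0588 (0.38 with an effective-length offset, adjusted p = 0.132). Wnt and beta-catenin target genes (median -0.53, 0 higher and 6 lower of 13) did not pass as a list (adjusted p = 0.0732, and 0.0202 over genes well above background, or 0.0997 there with an estimated correlation).

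Some B cell and plasma cell genes rose from few reads. Ighm, the IgM heavy chain, rose by 6.18 ± 0.0741 (230 to 75368 reads), the joining chain Jchain by 6.46 ± 0.177 (7.25 without isotype control replicate 2) and the light chain Iglc2 by 6.08 (7.30 without isotype control replicate 1). Plasma cell genes were higher in 4 and lower in 1 of 6, median 4.58 (adjusted p = 0.0313, adjusted p = 0.23 with an estimated correlation, and 0.0966 with background subtracted). Their median was 5.88, 5.78 or 5.52 without isotype control replicate 1, 2 or 3. B cell genes were higher in 2 and lower in 2 of 7 (adjusted p = 0.734). T cell genes were higher in 8 and lower in 3 of 19 (7 and 2 adjusted over the list alone), median 0.43 (adjusted p = 0.392). Cd3e, a chain of the T cell receptor complex, rose by 2.04 ± 0.486, and Trbc2, a receptor constant region, by 3.45 (4.86 without isotype control replicate 2). Natural killer cell genes were higher in 3 and lower in 3 of 13 (median 0.07, adjusted p = 0.83), and cytotoxic effector genes higher in 4 and lower in 1 of 7 (median 0.98, adjusted p = 0.606). The granzyme gene Gzma rose by 3.55 ± 0.358 (4.23 without isotype control replicate 1). Dendritic cell genes were higher in 8 and lower in 3 of 12, median 1.15 (adjusted p = 0.136, and 0.0183 over genes well above background, or 0.0641 there with an estimated correlation). Reads beyond background of the T cell, natural killer cell and cytotoxic effector lists, which lay at background in isotype control libraries (-10.72 ± 29.3, 2.793 ± 15 and -3.895 ± 4.36), were 175.2 ± 9.18, 158.9 ± 4.79 and 90.89 ± 2.47 in anti-B7-H3 libraries, and those of the B cell list 42.87 ± 26.3 and 5796 ± 36.6.

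Fibroblast genes rose in 14 of 14, median 1.53 (adjusted p = 2.71e-07). The collagen crosslinking enzyme Lox rose by 3.14 and Dpt, dermatopontin, by 2.48. Ribosomal protein genes were higher in 20 of 20, median 1.14 (adjusted p = 2.47e-09, and adjusted p = 0.105 with an estimated correlation). Hypoxia and glycolysis genes were higher in 14 and lower in 2 of 19, median 0.72 (adjusted p = 0.00133, adjusted p = 0.134 with an estimated correlation, 0.0697 over genes well above background and 0.473 with background subtracted). Proliferation genes were lower in 15 and higher in 2 of 24, median -0.55 (adjusted p = 0.0111, and adjusted p = 0.105 with an estimated correlation). The list was not called without anti-B7-H3 replicate 1 (-0.49, adjusted p = 0.0687) or replicate 3 (-0.41, adjusted p = 0.0716), and over genes well above background its median was -0.88 (adjusted p = 1.75e-06). The mitotic motor Kif11 fell by 1.21 and the cyclin Ccnb1 by 1.11, while the replication genes Pcna and Mcm4 rose by 0.44 and 0.38. Over genes well above background Pcna (0.11, adjusted p = 0.454) and Mcm4 (0.05, adjusted p = 0.777) did not pass, nor did Pcna without isotype control replicate 3 (0.23, adjusted p = 0.106) or Mcm4 without isotype control replicate 2 (0.22, adjusted p = 0.199).

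Genes of muscle, skin and mitochondria had lower fitted values, and the muscle and skin falls were smaller with background subtracted. Mitochondrially encoded genes fell in 13 of 13, median -2.25 (adjusted p = 1.53e-07, and adjusted p = 0.134 with an estimated correlation). The complex I gene mt-Nd2 fell by 3.84 and mt-Nd6 by 3.99. Skeletal muscle genes fell in 14 of 14 (adjusted p = 8.22e-07), with a fitted median of -5.37 (-6.51 without anti-B7-H3 replicate 2), or -4.94 with the 7 members of 3 or fewer reads at the floor. The myosin Myh4 had 100 reads in isotype control libraries against 128 from background, and 0 in anti-B7-H3. With background subtracted the skeletal muscle median was -0.33 (adjusted p = 0.00698), and the reads of the list beyond background were 569.6 ± 216 in isotype control and 83.37 ± 6.53 in anti-B7-H3 libraries. Keratinocyte genes fell in 7 of 7 (adjusted p = 0.000189), with a fitted median of -6.50, or -6.26 with the floor. That fitted median ran from -4.16 without isotype control replicate 1 to -8.32 without anti-B7-H3 replicate 3. With background subtracted the keratinocytes median was -4.94 (adjusted p = 0.0153), and reads beyond background were 48.75 ± 11 in isotype control and 8.928 ± 1.66 in anti-B7-H3 libraries. Pigment genes fell in 6 of 7 (adjusted p = 0.00647), with a median of -5.01, or -5.13 with the floor. Their median was -3.95, -3.81 or -4.02 without isotype control replicate 1, 2 or 3. Over the 2 genes well above background the pigment median was -1.37, with background subtracted it was -2.51 (adjusted p = 0.00365), and reads beyond background were 282.2 ± 32.6 in isotype control and 90.66 ± 5.48 in anti-B7-H3 libraries. Tyr, the rate-limiting enzyme of melanin synthesis, fell by 6.10 (5 reads in anti-B7-H3, 85 in isotype control against 35.2 from background) and stood at -5.45 without anti-B7-H3 replicate 1. Red blood cell genes were higher in 1 and lower in 2 of 5 (median -0.32, adjusted p = 0.663).

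By size, the leading genes with 0 reads in isotype control libraries were Ifi47, an interferon-induced GTPase (at least 60.1-fold higher), Lpin1, a phosphatidate phosphatase (at least 45.3-fold), the cytokine Tnfsf13 (at least 14.4-fold) and Cd300lb, a myeloid receptor (at least 11.4-fold), although background alone would give 15.9 to 60.9 reads. Their folds rest on the floor of 3 reads and would be smaller against background of that size. Leading in the other direction with 0 reads in anti-B7-H3 libraries were Duxf3 (at least 782-fold lower), the mucin Muc5ac (at least 540-fold) and Flg, filaggrin of the skin barrier (at least 478-fold). Background alone would give 44.5 of the 520 isotype control reads of Duxf3, 228 of 359 of Muc5ac and 23.5 of 318 of Flg, so the fold of Muc5ac may be largely background. Ttll10 and Rtl1 had 1 read each in anti-B7-H3 libraries, which gives ratios of 8190 (1470 to 324000) and 3610 (646 to 143000), from 1817 and 800 isotype control reads against 46.4 and 115 from background. Altogether 4148 genes were called higher and 4493 lower of 13478. Of these calls 48.0% were higher, against 35.3% without a filter, 78.1% with background subtracted and 37.9% at 2-fold or more (1824 higher and 2990 lower). Over the 8130 genes well above background 2431 were higher and 2430 lower, and the macrophage, MHC class I, interferon gamma response and fibroblast medians were 2.38, 2.59, 1.81 and 1.22. Some of these genes lie at background in isotype control libraries and are kept for their reads in other groups.

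**Figure D2:**
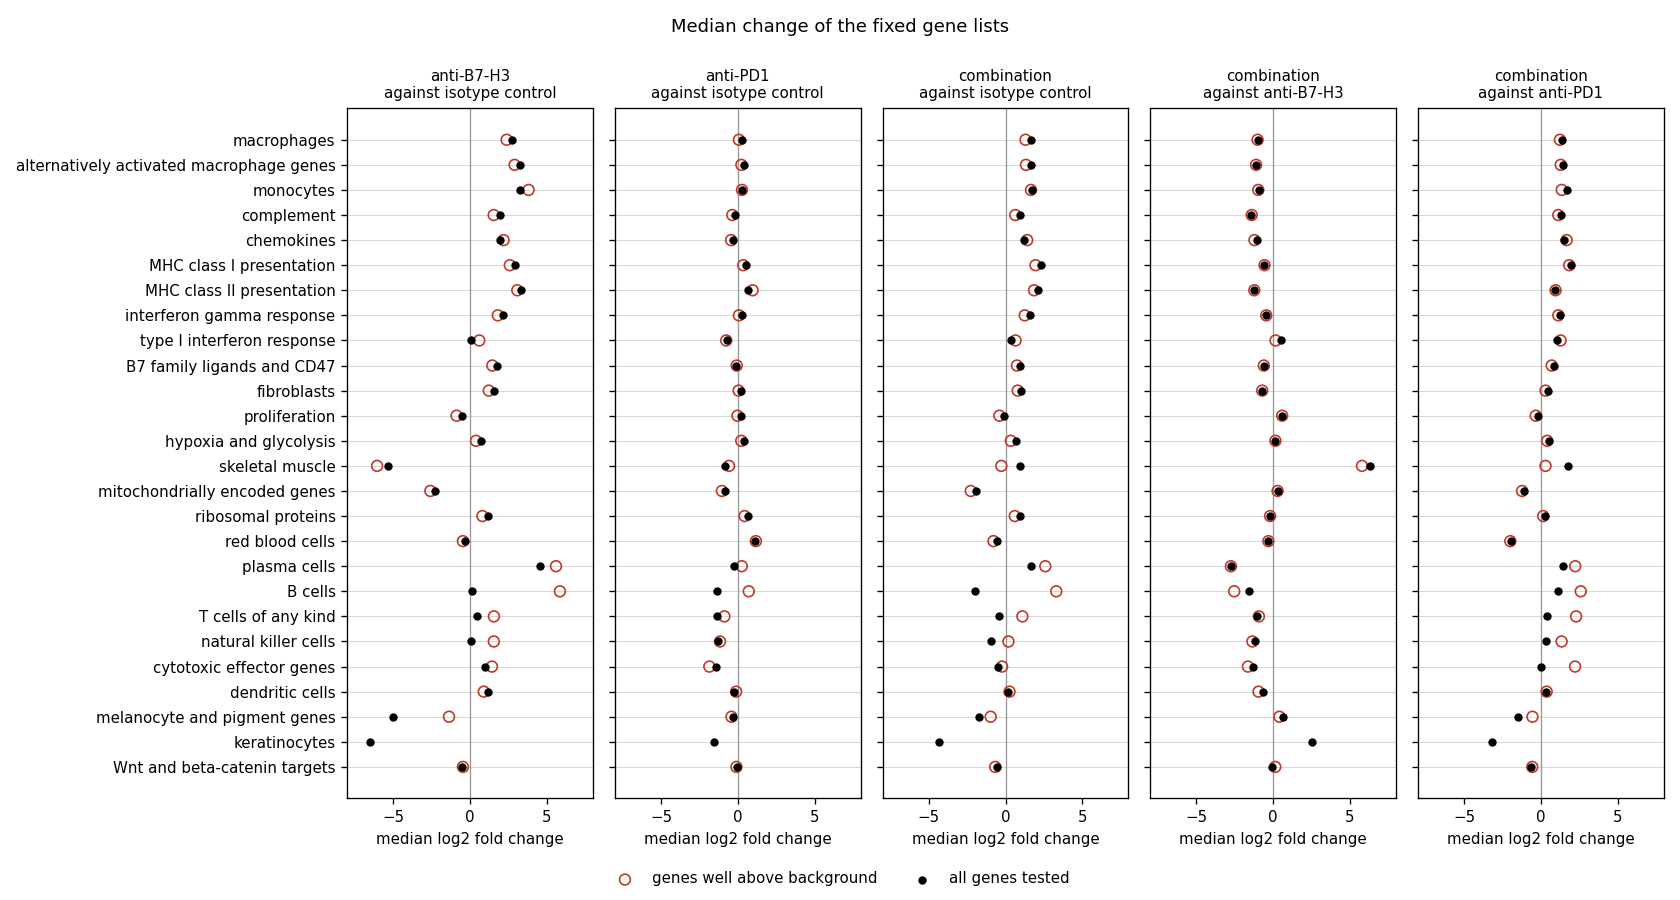
Median log2 fold change of 26 gene lists in the 5 comparisons (black, all genes tested; open red, genes well above background). For anti-B7-H3 against isotype control the macrophage median is 2.71 and 2.38 in these settings.

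Anti-PD1 was compared with isotype control (n = 3 each) to ask what blocking PD1 alone did. Fibroblast and antigen presentation genes were among those higher, by less than with anti-B7-H3 (the difference between these effects was not tested). Ribosomal protein genes rose in 20 of 20, median 0.65 (adjusted p = 2.63e-11). Rps9 rose by 1.0. MHC class II presentation genes were higher in 7 of 11 (7 higher and 1 lower adjusted over the list alone), median 0.68 (adjusted p = 0.000537). The invariant chain Cd74 rose by 1.27 ± 0.0605 and H2-DMa by 1.36 (0.69 with an effective-length offset, adjusted p = 0.0522). MHC class I presentation genes were higher in 8 of 14, median 0.56 (adjusted p = 0.00165, and 0.196 with background subtracted). H2-D1 rose by 1.21 and H2-K1 by 1.07. Red blood cell genes rose in 4 of 5, median 1.14 (adjusted p = 0.00774). The alpha globin Hba-a1 rose by 1.61. This list was not called with background subtracted (adjusted p = 0.0547) or with the satellite-like genes left out (adjusted p = 0.0781). Hypoxia and glycolysis genes were higher in 14 of 19, median 0.43 (adjusted p = 4.11e-05, and 0.32 with background subtracted). Ddit4, a stress-induced inhibitor of mTORC1, rose by 0.96. No list kept its call with an estimated correlation: adjusted p = 0.0984 for ribosomal proteins, 0.126 for MHC class II and 0.0822 for MHC class I, red blood cells and hypoxia.

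Macrophage genes were higher in 7 and lower in 1 of 16, median 0.27 (adjusted p = 0.00774, adjusted p = 0.0822 with an estimated correlation, and 0.312 over genes well above background). C1qc rose by 0.89 ± 0.0893. The lysosomal glycoprotein gene Cd68 fell by 0.47 and was not called without isotype control replicate 3 (-0.31, adjusted p = 0.251), without anti-PD1 replicate 3 (-0.33, adjusted p = 0.137) or without a filter (-0.31, adjusted p = 0.117). Alternatively activated macrophage genes were higher in 5 of 10 (6 adjusted over the list alone), median 0.44 (adjusted p = 0.0109, adjusted p = 0.119 with an estimated correlation, and 0.19 over genes well above background). Fibroblast genes were higher in 7 and lower in 2 of 14, median 0.23 (adjusted p = 0.0109, adjusted p = 0.138 with an estimated correlation, and 0.0774 over genes well above background). The collagens Col1a2 and Col1a1 rose by 1.71 ± 0.0572 and 1.51 ± 0.0576. Proliferation genes were higher in 9 of 24, median 0.18 (adjusted p = 0.0109, and adjusted p = 0.119 with an estimated correlation), but -0.02 over genes well above background (adjusted p = 0.945). The mitotic kinase Cdk1 rose by 0.77. Interferon gamma response genes were higher in 6 and lower in 1 of 17 (median 0.27, adjusted p = 0.147). Gbp6 rose by 2.83 (3.56 without isotype control replicate 3, and 1.5 with an effective-length offset, adjusted p = 0.306), and Gbp5 fell by 2.06. Complement genes (median -0.16, 1 higher and 3 lower of 12, adjusted p = 0.394) passed over genes well above background (-0.36, adjusted p = 0.00415, and adjusted p = 0.0714 with an estimated correlation). Chemokine genes (median -0.31, or -0.56 with the floor, 2 higher and 2 lower of 16, 2 and 1 adjusted over the list alone, adjusted p = 0.932) did not pass, although Ccl8 rose by 1.12.

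Most lymphocyte lists had negative medians, although their reads beyond background were not lower than in isotype control libraries. T cell genes were lower in 10 of 19 (11 adjusted over the list alone), median -1.33 (adjusted p = 0.00144, adjusted p = 0.0822 with an estimated correlation, and 0.157 over genes well above background), with 162 ± 30.4 reads per anti-PD1 library against 117 from background. With background subtracted the median was -0.74 (adjusted p = 0.0475), while reads of the T cell list beyond background stood at -10.72 ± 29.3 in isotype control and 17.7 ± 10.3 in anti-PD1 libraries. Cd3g, of the T cell receptor complex, fell by 2.46 (-3.26 without anti-PD1 replicate 2, and not called with background subtracted, adjusted p = 0.088), from 16 reads to 8. Natural killer cell genes were lower in 8 of 13 (9 adjusted over the list alone), median -1.31, or -1.32 with the floor (adjusted p = 0.00774, adjusted p = 0.0822 with an estimated correlation), and 0.32 with background subtracted. Type I interferon response genes were lower in 11 of 22 (1 higher and 11 lower adjusted over the list alone), median -0.73 (adjusted p = 0.001, and adjusted p = 0.0822 with an estimated correlation), and 0.56 with background subtracted. B cell genes were lower in 5 and higher in 1 of 7 (6 and 1 adjusted over the list alone, median -1.38, adjusted p = 0.0975). The list passed without isotype control replicate 1 (-1.60, adjusted p = 0.0164) and without anti-PD1 replicate 1, 2 or 3 (-1.47, -1.67 and -1.29, adjusted p = 0.0315, 0.0165 and 0.0267). With background subtracted the B cells median was -0.08 (adjusted p = 0.314), and reads of the whole list beyond background went the other way, 42.87 ± 26.3 in isotype control and 162.1 ± 17.2 in anti-PD1 libraries. Cytotoxic effector genes were lower in 4 of 7 (5 adjusted over the list alone, median -1.39, adjusted p = 0.0591) and passed without isotype control replicate 3 (-1.68, adjusted p = 0.0285), with reads beyond background of -3.895 ± 4.36 in isotype control and 13.21 ± 7.48 in anti-PD1 libraries. Plasma cell (median -0.28, adjusted p = 0.932, or 2.13 with background subtracted, adjusted p = 0.672), monocyte (0.27, adjusted p = 0.898) and dendritic cell genes (-0.27, adjusted p = 0.748) did not pass.

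Mitochondrially encoded genes fell in 12 of 13, median -0.83 (adjusted p = 1.49e-06, and adjusted p = 0.156 with an estimated correlation). mt-Nd2 fell by 1.52. Skeletal muscle genes were lower in 8 of 14 (9 adjusted over the list alone), median -0.84, or -0.83 with the floor (adjusted p = 0.00774, adjusted p = 0.0822 with an estimated correlation), and 0.62 with background subtracted. Keratinocyte genes were lower in 6 of 7, median -1.53 (adjusted p = 0.00774, and adjusted p = 0.0822 with an estimated correlation). That list was not called without isotype control replicate 1 (-1.20, adjusted p = 0.0627) or anti-PD1 replicate 1, 2 or 3 (-1.08, -1.01 and -1.05, adjusted p = 0.0535, 0.0967 and 0.0791), nor with background subtracted (-0.73, adjusted p = 0.314). Its reads beyond background were 48.75 ± 11 in isotype control and 55.05 ± 13 in anti-PD1 libraries, so a fall beyond background is not supported. Subtracting background also ended the calls of the macrophage, alternatively activated macrophage, fibroblast and proliferation lists in this comparison. Pigment genes (median -0.28, adjusted p = 0.179), Wnt targets (median -0.04, mean -0.27, upward test, adjusted p = 0.998) and B7 ligands (median -0.13, mean -0.01, upward test, adjusted p = 0.69) did not pass. Of the targets, Cd276 rose by 0.89 ± 0.176, Cd47 by 0.61 ± 0.132, Sirpa by 0.47 ± 0.141 (not called without isotype control replicate 2, 0.36, adjusted p = 0.084, or over genes well above background, 0.27, adjusted p = 0.196) and Ctnnb1 by 0.45 ± 0.0612 (0.07 with an effective-length offset, adjusted p = 0.829). Pdcd1 (-1.12 ± 0.757, adjusted p = 0.25), Cd274 (-0.28 ± 0.311, adjusted p = 0.507) and Pdcd1lg2 (-0.13 ± 0.333, adjusted p = 0.792) did not pass. With 0 reads in isotype control, Lpin1 was at least 42.5-fold, Ifi47 at least 12.2-fold and Tnfsf13 at least 5.62-fold higher against the floor. Expected background exceeds 3 isotype control reads of each, unlike the 0 seen, and would make these folds smaller. The beta globin Hbb-bt had 2 reads against 94, a ratio of 16.5 (4.44 to 138). Crabp1, a retinoic acid binding protein, rose by 3.04 (4.27 without isotype control replicate 1). Zfp978 fell by 3.51, Calhm6 by 3.25 (-4.75 without anti-PD1 replicate 2), Ttll11 by 3.06 and Mbnl3 by 3.03. The B cell receptor gene Cd79b fell by 3.11 (-2.50 without isotype control replicate 3, -3.80 without anti-PD1 replicate 2, and not called with background subtracted, adjusted p = 0.0512). Each of these 5 had 5 to 26 reads over the anti-PD1 libraries. In total 2353 genes were higher and 2811 lower (45.6% higher, against 37.1% without a filter, 87.4% with background subtracted and 7.71% at 2-fold or more, 167 against 1999), or 988 and 941 over genes well above background.

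The combination was compared with isotype control (n = 3 each) to ask what both antibodies did together. Macrophage genes were higher in 16 of 16, median 1.63 (adjusted p = 7.91e-09). Mrc1 rose by 2.37 ± 0.0646 and C1qc by 2.22 ± 0.0783. MHC class I presentation genes were higher in 14 of 14, median 2.28 (adjusted p = 1.31e-08). H2-K1 rose by 3.6 and H2-D1 by 3.25. Alternatively activated macrophage genes were higher in 9 of 10, median 1.66 (adjusted p = 2.96e-06). Mgl2 rose by 2.40 and the eosinophil attractant Ccl24 by 2.53. Interferon gamma response genes were higher in 14 and lower in 1 of 17, median 1.58 (adjusted p = 6.32e-05). The GTPase Iigp1 rose by 2.39 and Gbp6 by 3.99 (4.72 without isotype control replicate 3, and 2.26 with an effective-length offset, adjusted p = 0.0748). Complement genes were higher in 8 of 12, median 0.93 (adjusted p = 0.000535). C3 rose by 2.79. MHC class II presentation genes were higher in 8 and lower in 1 of 11 (8 and 2 adjusted over the list alone), median 2.09 (adjusted p = 0.000189, and adjusted p = 0.116 with an estimated correlation). H2-Ab1 rose by 2.48 and H2-Eb1 by 2.54. Fibroblast genes were higher in 10 of 14 (11 adjusted over the list alone), median 1.01 (adjusted p = 8.4e-05, and adjusted p = 0.0565 with an estimated correlation). Lox rose by 1.75. Monocyte genes were higher in 5 of 6, median 1.70 with or without the floor (adjusted p = 0.0168, adjusted p = 0.099 with an estimated correlation, and 0.0641 with background subtracted). B7 ligands and Cd47 were higher in 6 of 9 (7 adjusted over the list alone), median 0.97 (adjusted p = 0.0199, adjusted p = 0.0844 with an estimated correlation, and 0.0884 with background subtracted).

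Ribosomal protein genes rose in 20 of 20, median 0.93 (adjusted p = 2.86e-09, and adjusted p = 0.115 with an estimated correlation). Rps9 rose by 1.47. Hypoxia and glycolysis genes rose in 14 of 19, median 0.68 (adjusted p = 1.21e-05, adjusted p = 0.0653 with an estimated correlation, and 0.0884 with background subtracted). Mitochondrially encoded genes fell in 13 of 13, median -1.93 (adjusted p = 2.55e-08, and adjusted p = 0.116 with an estimated correlation). mt-Nd2 fell by 3.53. Keratinocyte genes fell in 7 of 7, median -4.30, or -4.32 with the floor (adjusted p = 6.91e-05). Pigment genes were lower in 5 of 7, median -1.76, or -1.77 with the floor (adjusted p = 0.00464, and adjusted p = 0.0565 with an estimated correlation). Wnt and beta-catenin targets were lower in 9 of 13, median -0.58 (adjusted p = 0.0335, and adjusted p = 0.116 with an estimated correlation), and 0.42 with background subtracted. They were not called without a filter (adjusted p = 0.344), with the offset (0.0964), without satellite-like genes (0.23), without isotype control replicate 3 (-0.52, 0.1) or without combination replicate 2 (-0.49, 0.051). Skeletal muscle genes were higher in 9 and lower in 2 of 14, median 0.95, or 0.96 with the floor, and did not pass (adjusted p = 0.0839, or 0.0263 with background subtracted, median 3.59), while the actin Acta1 rose by 1.90. Proliferation genes (5 higher and 6 lower of 24) had a median of -0.07 (mean -0.01, upward test, adjusted p = 0.963). It was -0.40 over genes well above background (adjusted p = 0.00309) and 0.06 with background subtracted (adjusted p = 0.0132). Pcna rose by 0.53 (0.21 over genes well above background, adjusted p = 0.168). The mitotic checkpoint kinase Bub1 fell by 0.40 and was not called without a filter (-0.10, adjusted p = 0.497), with background subtracted (-0.07, 0.698), without satellite-like genes (-0.13, 0.357) or with the offset (-0.30, 0.0512).

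Chemokine genes were higher in 7 and lower in 2 of 16, median 1.18, or 0.82 with the floor, and did not pass (adjusted p = 0.0731), but passed without isotype control replicate 1 (1.44, adjusted p = 0.0368) or replicate 2 (1.22, adjusted p = 0.0328) and over genes well above background (1.41, adjusted p = 0.00409). Ccl8 rose by 3.50. Type I interferon response genes were higher in 11 and lower in 3 of 22, median 0.34 (adjusted p = 0.0839), and passed without combination replicate 1 (0.42, adjusted p = 0.0483) or replicate 3 (0.48, adjusted p = 0.0412) and over genes well above background (0.65, adjusted p = 0.0448, and adjusted p = 0.0867 with an estimated correlation) or with background subtracted (2.70, adjusted p = 0.0132). The ubiquitin-like Isg15 rose by 1.79 and the nucleic acid sensor Zbp1 by 1.72. Plasma cell (median 1.66, adjusted p = 0.299, and 0.0225 over genes well above background, or 0.178 there with an estimated correlation), B cell (-1.96, 0.457), T cell (-0.42, 0.264), natural killer cell (-0.95, 0.256), cytotoxic effector (-0.47, 0.616), red blood cell (-0.53, 0.366) and dendritic cell genes (median 0.15, mean -0.12, upward test, 0.739) did not pass. Reads beyond background went up instead, from 42.87 ± 26.3 to 1011 ± 19.5 for B cells, -10.72 ± 29.3 to 79.17 ± 6.01 for T cells, 2.793 ± 15 to 71.11 ± 2.68 for natural killer cells and -3.895 ± 4.36 to 35.32 ± 2.56 for cytotoxic effectors. Single members rose: Ighm by 3.63, Jchain by 3.87 (4.65 without isotype control replicate 2), Trbc2 by 2.51 (3.92 without isotype control replicate 2) and Gzma by 1.62 (2.30 without isotype control replicate 1, and 1.05 without replicate 3, adjusted p = 0.0543). Of the targets, Cd276 rose by 0.96 ± 0.17, Cd274 by 0.97 ± 0.257, Pdcd1lg2 by 1.07 ± 0.275, Cd47 by 1.31 ± 0.119, Sirpa by 1.78 ± 0.117 and Ctnnb1 by 0.61 ± 0.0596 (-0.02 with an effective-length offset, adjusted p = 0.949). Pdcd1 stood at 0.38 ± 0.615 (adjusted p = 0.619). With 0 reads in isotype control, Ifi47 was at least 44.3-fold, Lpin1 at least 35.5-fold, Tnfsf13 at least 9.67-fold and Cd300lb at least 5.85-fold higher against the floor. Expected background exceeds 3 isotype control reads of each, unlike the 0 seen, and would make these folds smaller. The GTPase Tgtp2 rose by 4.39 (3.68 and 5.18 without isotype control replicate 1 and 2). With 0 reads in combination libraries, Prol1 was at least 160-fold lower (122 isotype control reads against 20.6 from background). Gp1ba and the odorant receptor Olfr635, with 1 read each, gave ratios of 373 (65.4 to 14900) and 334 (58.4 to 13300), from 95 and 85 isotype control reads against 48.4 and 21.2 from background, and the mucin Muc6 fell by 9.40. In total 3745 genes were higher and 3982 lower (48.5% higher, against 36.1% without a filter, 83.6% with background subtracted and 28.2% at 2-fold or more), or 1891 and 1890 over genes well above background.

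The combination was compared with anti-B7-H3 alone (n = 3 each) to ask what adding anti-PD1 changed, and these libraries hold the least background. Macrophage genes were lower in the combination, 15 of 16 (16 adjusted over the list alone), median -1.02 (adjusted p = 8.86e-13). Cd68 fell by 1.29 ± 0.0795 and Ms4a7 by 1.14 ± 0.0896. Alternatively activated macrophage genes fell in 10 of 10, median -1.12 (adjusted p = 1.07e-11). Chil3 fell by 3.0 ± 0.0478 and the resistin-like Retnla by 2.42 ± 0.1. Complement genes fell in 12 of 12, median -1.46 (adjusted p = 4.2e-12). C3 fell by 2.42 and the protease Cfd by 2.16. MHC class II presentation genes fell in 10 of 11, median -1.24 (adjusted p = 1.98e-10). H2-Aa fell by 1.39. MHC class I presentation genes fell in 14 of 14, median -0.57 (adjusted p = 1.92e-05). The immunoproteasome gene Psmb8 fell by 0.75 and the peptide loading gene Tapbp by 0.73. Interferon gamma response genes were lower in 14 and higher in 1 of 17, median -0.46 (adjusted p = 0.000219), with the T cell attractant Cxcl9 at -1.43 and Socs1 at -1.28, while Gbp5 rose by 0.69. Type I interferon response genes went the other way, 10 higher and 1 lower of 22, median 0.49 (adjusted p = 0.00708), but 0.15 over genes well above background (adjusted p = 0.207). Ifi44 and Ifit3 rose by 1.60 and 1.46, and Zbp1 fell by 0.53. Monocyte genes fell in 5 of 6, median -0.91 (adjusted p = 0.00201), and chemokine genes in 10 of 16 with 1 higher (10 and 1 adjusted over the list alone), median -1.07 with or without the floor (adjusted p = 0.000143). Cxcl12 fell by 2.28, and Cx3cl1 rose by 0.69.

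Lymphocyte genes were lower too. Plasma cell genes fell in 5 of 6 (6 adjusted over the list alone), median -2.76 (adjusted p = 7.69e-06), with Iglc2 at -3.32, and B cell genes in 6 of 7, median -1.60 (adjusted p = 0.000168), with Ighm at -2.55 ± 0.0504 (75368 to 11235 reads). T cell genes fell in 14 of 19 (15 adjusted over the list alone), median -1.09 (adjusted p = 1.23e-05), with Trbc1 at -1.89, and natural killer cell genes in 8 of 13, median -1.21 (adjusted p = 0.00111), with Gzma at -1.93. Cytotoxic effector genes fell in 4 of 7, median -1.33 (adjusted p = 0.00658, and adjusted p = 0.0633 with an estimated correlation). Gzmb fell by 1.66. Over genes well above background 3 members of each of these last 3 lists were left, and no list passed (medians -0.93, -1.36 and -1.65, adjusted p = 0.207, 0.207 and 0.0529). Dendritic cell genes fell in 8 of 12, median -0.67 (adjusted p = 0.000692). Fibroblast genes fell in 13 of 14, median -0.73 (adjusted p = 2.23e-09). Decorin, Dcn, fell by 1.49. B7 ligands and Cd47 were lower in 7 and higher in 1 of 9, median -0.62 (adjusted p = 0.00283).

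Skeletal muscle genes rose in 14 of 14 (adjusted p = 9.5e-20), with a fitted median of 6.32, or 5.53 (46.1-fold) with the 7 members of 3 or fewer reads at the floor. Muscle taken along with tumours was not tested as a cause in any comparison. The myosin Myh4 was at least 525-fold higher (0 against 1373 reads), Xirp2 at least 122-fold and the troponin Tnnc2 at least 52.4-fold. Acta1 had 1 read against 824, a ratio of 945 (169 to 37400), and Myh1 2 reads against 573, a ratio of 329 (90.6 to 2720). Proliferation genes were higher in 18 of 24, median 0.58 (adjusted p = 2.57e-07). Kif11 rose by 0.91 and Ccnb1 by 0.79. Mitochondrially encoded genes were higher in 11 of 13 (12 higher and 1 lower adjusted over the list alone), median 0.28 (adjusted p = 0.00115, and adjusted p = 0.281 with an estimated correlation), and ribosomal protein genes lower in 18 of 20 (19 adjusted over the list alone), median -0.21 (adjusted p = 0.000197, and adjusted p = 0.233 with an estimated correlation). Hypoxia genes were higher in 10 and lower in 1 of 19, median 0.14 (adjusted p = 0.0383, and adjusted p = 0.273 with an estimated correlation). The carbonic anhydrase Car9 rose by 1.42. That list was not called without anti-B7-H3 replicate 2 or 3 (0.13 and 0.14, adjusted p = 0.0787 and 0.061) or combination replicate 1, 2 or 3 (0.16, 0.12 and 0.14, adjusted p = 0.0525, 0.0897 and 0.0606). Pigment (median 0.65, or 0.27 with the floor, adjusted p = 0.167), keratinocyte (2.50, or 0.20 with the floor, 0.287), red blood cell (-0.37, 0.473) and Wnt target lists (-0.05, 0.911) did not pass, although Tyr rose by 4.34 (5.0 without anti-B7-H3 replicate 3) and the melanocyte factor Sox10 by 1.25.

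Of the targets, Pdcd1lg2 fell by 1.90 ± 0.117, Sirpa by 1.05 ± 0.0569, Cd274 by 0.83 ± 0.133 and Cd47 by 0.47 ± 0.0658, and Cd276 rose by 0.41 ± 0.104. Ctnnb1 fell by 0.13 ± 0.0458 (adjusted p = 0.0156) and was not called without anti-B7-H3 replicate 1, 2 or 3 (-0.11, -0.13 and -0.11, adjusted p = 0.13, 0.0547 and 0.146) or combination replicate 1 or 2 (-0.13 and -0.10, adjusted p = 0.0702 and 0.194). Pdcd1 stood at -0.31 ± 0.388 (adjusted p = 0.575). Among the leading lower genes, C1qtnf3 fell by 3.82 and the IgA heavy chain Igha by 3.79. The IgE heavy chain Ighe had 31 reads against 2, a ratio of 13.5 (3.44 to 117). Arhgap39 fell by 4.94 and lost its call without anti-B7-H3 replicate 2 (-4.56, adjusted p = 0.05) or combination replicate 1 or 3 (-4.39 and -5.26, adjusted p = 0.0599 and 0.0574). The urinary protein gene Mup22 was at least 25.3-fold lower (87 against 0 reads), with an adjusted p of 0.0635 to 0.0803 when any of the 6 libraries was left out. With an effective-length offset Cd276 (adjusted p = 0.465), Ctnnb1 (0.196), Arhgap39 (0.13), Cx3cl1 (0.429), Psmb8 (0.0508), Tapbp (0.0671) and Dcn (0.461) were not called. In total 2675 genes were higher and 2579 lower, or 1764 and 1878 over genes well above background.

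**Figure D3:**
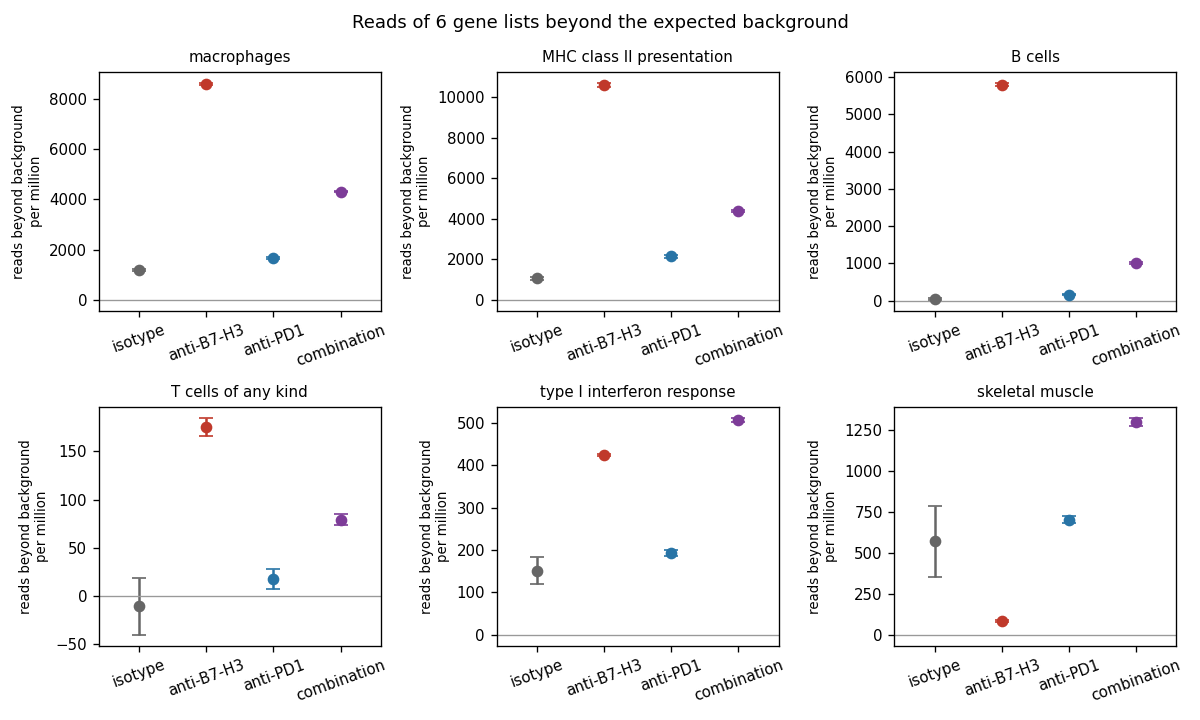
Reads beyond expected background, per 1e6 of the library total after TMM scaling over the genes well above background, for 6 gene lists in the 4 groups (mean ± SD, n = 3). Macrophage genes hold 1193 ± 54.0 in isotype control, 8576 ± 41.8 in anti-B7-H3, 1662 ± 38.4 in anti-PD1 and 4308 ± 18.8 in combination libraries.

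The combination was compared with anti-PD1 alone (n = 3 each) to ask what adding anti-B7-H3 changed. Macrophage genes were higher in 16 of 16, median 1.36 (adjusted p = 8.72e-13). Mrc1 rose by 1.87 ± 0.0519 and the lysozyme Lyz2 by 1.88 ± 0.0584. MHC class I presentation genes were higher in 14 of 14, median 1.97 (adjusted p = 7.69e-12). H2-Q6 rose by 2.65 and H2-K1 by 2.53. Type I interferon response genes were higher in 18 of 22, median 1.07 (adjusted p = 1.03e-08). The antiviral Oas1a rose by 2.78 and Ifi44 by 2.61. Interferon gamma response genes were higher in 15 and lower in 1 of 17, median 1.25 (adjusted p = 2.05e-06). Gbp4 rose by 2.04 and Iigp1 by 2.12, and Gbp5 fell by 2.30. Complement genes were higher in 11 of 12, median 1.30 (adjusted p = 2.82e-08). C3 rose by 2.62 and Cfp by 1.69. Alternatively activated macrophage genes were higher in 8 of 10, median 1.42 (adjusted p = 1.18e-06). The arginase Arg1 rose by 1.92 and the lectin Clec10a by 2.08. Monocyte genes rose in 6 of 6, median 1.70 (adjusted p = 0.000345), and chemokine genes in 10 of 16 with 2 lower (11 and 2 adjusted over the list alone), median 1.53, or 1.55 with the floor (adjusted p = 0.000836). Ccl8 rose by 2.39 and Ccl12 by 2.34. MHC class II presentation genes were higher in 9 of 11, median 0.94 (adjusted p = 3.12e-05, and adjusted p = 0.0696 with an estimated correlation). The protease Ctss rose by 1.57 and H2-Eb1 by 1.35. B7 ligands and Cd47 were higher in 6 of 9, median 0.82 (adjusted p = 0.00204).

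Fibroblast genes were higher in 9 of 14, median 0.47 (adjusted p = 0.00141, and adjusted p = 0.0638 with an estimated correlation). Dpt rose by 2.16 and Fap by 1.63 (1.22 with an effective-length offset, adjusted p = 0.103). Skeletal muscle genes were higher in 12 and lower in 1 of 14, median 1.78, or 1.79 with the floor (adjusted p = 2.02e-05). The troponin Tnni2 rose by 2.66, and parvalbumin, Pvalb, had 1 read against 42, a ratio of 30.4 (5.17 to 1230). Red blood cell genes fell in 5 of 5, median -1.96 (adjusted p = 0.000451). Hba-a1 fell by 2.0. Keratinocyte genes fell in 7 of 7, median -3.17, or -3.19 with the floor (adjusted p = 6.75e-06). Pigment genes were lower in 5 of 7, median -1.47 with or without the floor (adjusted p = 0.00273), and Wnt targets in 8 of 13 (9 adjusted over the list alone), median -0.62 (adjusted p = 0.00244). Mitochondrially encoded genes fell in 13 of 13, median -1.10 (adjusted p = 2.04e-09, and adjusted p = 0.0837 with an estimated correlation). mt-Nd2 fell by 2.0. Ribosomal protein genes were higher in 19 of 20 (20 adjusted over the list alone), median 0.27 (adjusted p = 2.86e-05, and adjusted p = 0.23 with an estimated correlation), and hypoxia genes higher in 14 and lower in 4 of 19, median 0.53 (adjusted p = 0.00164, and adjusted p = 0.123 with an estimated correlation). Proliferation genes were lower in 10 of 24, median -0.22 (adjusted p = 0.0225, and adjusted p = 0.121 with an estimated correlation). Kif11 fell by 0.52 and the mitotic kinase Plk1 by 0.51 (a fall of 0.45 with an effective-length offset, adjusted p = 0.195). That list was not called without combination replicate 1, 2 or 3 (-0.21, -0.17 and -0.17, adjusted p = 0.0867, 0.13 and 0.145), without a filter (-0.08, 0.863), with the offset (-0.19, 0.0645) or without satellite-like genes (-0.13, 0.533).

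Lymphocyte lists leaned higher without passing over all genes tested. T cell genes were higher in 7 of 19, median 0.38 (adjusted p = 0.0892), and passed without anti-PD1 replicate 2 (0.37, adjusted p = 0.0258) and over genes well above background, which keep 3 of the members (2.29, adjusted p = 0.0188, and adjusted p = 0.0665 with an estimated correlation). Those 3 are kept for their reads over all libraries, so they say little of the other members. Plasma cell genes were higher in 4 and lower in 1 of 6, median 1.45 (adjusted p = 0.076), and passed without anti-PD1 replicate 1 (2.06, adjusted p = 0.0255) and over genes well above background (2.23, adjusted p = 0.00375, and adjusted p = 0.0975 with an estimated correlation). B cell (median 1.08, adjusted p = 0.454), natural killer cell (0.31, or 0.29 with the floor, 0.486), cytotoxic effector (0.02, 0.263, and 0.0361 over the 3 genes well above background, or 0.16 there with an estimated correlation) and dendritic cell genes (0.31, 0.266) did not pass. With background subtracted T cell (2.83, adjusted p = 2.03e-05), natural killer cell (2.01, 0.0115), cytotoxic effector (3.54, 0.0176) and plasma cell genes (2.45, 0.0226) passed. In anti-PD1 libraries Gzma and Trbc2 held 7 reads each and Nkg7 and Cd3g 8 each, against 12.3, 8.23, 7.85 and 8.65 from background. Igkc and Jchain rose by 3.01 each, the IgG heavy chain Ighg2b by 3.56, Gzma by 3.27, the cytotoxic granule gene Nkg7 by 2.35, Cd3g by 2.42 (3.19 without anti-PD1 replicate 2) and Trbc2 by 3.19 (2.58 and 7.60 without anti-PD1 replicate 1 and 2). Apol9a rose by 3.21 and the myeloid receptor Cd300ld by 3.20. With 0 reads in combination libraries, the keratin Krt6a was at least 62.1-fold, Fam196a at least 44.6-fold and Prol1 at least 35.4-fold lower (135, 97 and 77 anti-PD1 reads against 26.2, 22.3 and 14.8 from background), and Muc6 fell by 7.68. Of the targets, Cd274 rose by 1.25 ± 0.192, Pdcd1lg2 by 1.20 ± 0.196, Cd47 by 0.70 ± 0.0802 and Sirpa by 1.31 ± 0.0787, and Cd276 stood at 0.07 ± 0.109 (adjusted p = 0.618). Pdcd1 rose by 1.5 ± 0.537 (adjusted p = 0.0173, 9 and 36 reads, where background alone would give 13.7 in anti-PD1 libraries), with 2.39 without anti-PD1 replicate 1, and was not called without anti-PD1 replicate 2 or 3 (1.09 and 1.31, adjusted p = 0.129 and 0.0733), without combination replicate 3 (1.28, adjusted p = 0.094) or by DESeq2 (adjusted p = 0.053). Ctnnb1 rose by 0.16 ± 0.0482 and was not called without anti-PD1 replicate 3 (0.11, adjusted p = 0.106) or over genes well above background (0.03, adjusted p = 0.589), and stood at -0.09 with an effective-length offset (adjusted p = 0.777). In total 3120 genes were higher and 3151 lower (49.8% higher, against 38.8% without a filter, 60.8% with background subtracted and 34.0% at 2-fold or more), or 1980 and 1948 over genes well above background.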

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

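The tests of a uniform background rate in the combination libraries, of chemoreceptor genes without reads, of mitochondrial DNA, of 1 RNA pool and of the macrophage pattern were chosen only after the results were seen. The tests of genomic DNA, of a few transcribed chemoreceptor genes and of other splits of the libraries were set earlier.

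The effect of both antibodies differed from the sum of the log2 effects of each for 4900 of 13478 genes, 2571 with a positive and 2329 with a negative interaction (edgeR), or 2704 over genes well above background. With background subtracted the balance was 894 positive and 4554 negative (16.4% positive), and at 2-fold or more 1792 and 711 (71.6%). The interaction was negative for macrophage genes (median -1.22, 14 lower of 16, adjusted p = 5.07e-10), with C1qc at -1.93 ± 0.0986 and C1qa at -1.74, and for alternatively activated macrophage genes (-1.96, 10 of 10), with Chil3 at -2.79 and Retnla at -2.58. It was negative for MHC class II presentation (-1.83, 9 of 11), with H2-Aa at -2.55, for MHC class I presentation (-1.11, 11 of 14), with H2-D1 at -1.72, and for complement (-0.92, 9 of 12), with C3 at -2.59. It was negative for interferon gamma response genes (-0.73, 10 lower and 1 higher of 17, 11 and 1 adjusted over the list alone), with Gbp6 at -3.86 (-4.60 without isotype control replicate 3, and -2.34 with an effective-length offset, adjusted p = 0.153) and Gbp5 at 2.75, and for fibroblast genes (-1.27, 11 lower and 1 higher of 14), with Col1a2 at -2.43 and Lox at -2.30. Skeletal muscle genes had a positive interaction (fitted median 7.57, 14 of 14), 6.98 without anti-B7-H3 replicate 1 and 3.24 with background subtracted, and a median that rests on genes at 0 reads is no bound. Type I interferon response genes stood at 1.53 (14 higher and 1 lower of 22, 15 and 1 adjusted over the list alone), but at -0.39 with background subtracted. Those values come beside 365.1 reads per isotype control library against 246 from background. Among the targets the interaction was -1.77 ± 0.338 for Pdcd1lg2, -1.08 ± 0.146 for Cd47, -1.52 ± 0.147 for Sirpa and -0.58 ± 0.0765 for Ctnnb1 (-0.48 with an effective-length offset, adjusted p = 0.263). Of 60 splits of the libraries 1, the real one, gave as many genes as 4900, and the highest other gave 3327. With 10 splits of 3 against 3 libraries a share under 0.05 cannot be reached, so only values are given for the 5 comparisons: 1 of 10 splits, the real one, gave 8641, 5164, 7727, 5254 and 6271 genes, and the highest other gave 0, 2, 0, 2 and 1. Each split used the same edgeR test.

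Background reads and satellite-like reads differ between groups. In isotype control libraries the share of chemoreceptor genes with a read lay within 6.44 percentage points of a uniform rate per base. This fits genomic DNA carried into the libraries, although nearly all genes have a read and the measure is near its upper limit. Anti-PD1 libraries lay 10 to 12.72 points from a uniform rate, and anti-B7-H3 libraries 6.5 to 7.54 points, with 2.071% to 2.654% of these genes holding a read where 8.566% to 9.87% were expected. The ratio of mt-Nd6 to mt-Co1 reads per kilobase, 12.4 times that of anti-B7-H3 libraries, fits mitochondrial DNA that came along. The 5% of chemoreceptor genes with the most reads carried 39.7% of their reads, between the limits set for and against transcription of a few of them, while 93.4% or more of these genes had a read in each isotype control library, which argues against reads from a few genes alone. Combination libraries departed from a uniform rate by at least 26.14 points, and the anti-PD1 gap is at or over the 10 points allowed for isotype control. Genomic DNA thus stays a candidate only, reads shared among similar genes were not tested, and background goes with the treatment group.

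The highest median chi-square between libraries of anti-B7-H3 or of combination was 0.58, little above counting noise (0.455). This fits 1 RNA pool sequenced as 3 libraries. Mean values reached 1.5 there and 4.39 in isotype control, so some genes varied more. No competing explanation, such as very similar tumours, was tested. If the libraries share a pool, a difference between groups may be a difference between pools.

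Macrophage genes were higher with anti-B7-H3 than with isotype control. Background reads added to isotype control libraries would shrink this difference, and could enlarge it only through library totals or scaling. With expected background taken from the totals only and no TMM scaling, the median log2 ratio of shares over the 16 genes was 3.19. The ratio of their summed reads was 3.31 to 3.48 over 9 pairs of libraries, against a fitted median of 2.71. Background reads therefore do not account for the difference. A lower share of tumour cells would raise fibroblast genes alike, and they rose, so it could explain part of the rise. The macrophage median was 1.16 above theirs (2.38 over 16 genes and 1.22 over 13, permutation of genes p = 0.00073, two-sided, 100000 resamples). A change in macrophages with treatment stays a hypothesis, as libraries of 1 pool may carry a difference between single tumours.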

How the results depend on the processing

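Settings that keep genes well above background, subtract background or leave out 12 satellite-like genes were chosen after the results were seen. Of 183 counts of calls under alternatives 152 stayed within 1.5 times and 31 moved. Without a filter 16711 (anti-B7-H3 against isotype control), 10021 (anti-PD1 against isotype control), 15865 (combination against isotype control), 11406 (combination against anti-PD1) and 7352 genes (interaction) were called. Over genes well above background, where fewer genes were tested, the counts were 4861, 1929, 3781, 3928 and 2704. At 2-fold or more they were 4814, 2166, 3815, 1450 (combination against anti-B7-H3), 2131 and 2503. An effective-length offset gave 2370 for combination against anti-B7-H3, 3521 for combination against anti-PD1 and 2868 for the interaction, and leaving out satellite-like genes gave 8566 for anti-PD1 against isotype control. Camera with an estimated correlation called 12, 0, 6 and 15 lists for anti-B7-H3, anti-PD1 and combination against isotype control and combination against anti-PD1, where fry, which asks another question, called 38, 32, 36 and 36. Over genes well above background camera called 8 lists for anti-PD1 against isotype control and 19 for combination against anti-B7-H3, and with background subtracted 4 for anti-PD1 against isotype control. Among called values the direction turned for Ctnnb1 with an effective-length offset (-0.02 for combination against isotype control, -0.09 against anti-PD1) and for proliferation over genes well above background (-0.02, anti-PD1 against isotype control). With background subtracted it turned for type I interferon response (0.56), skeletal muscle (0.62) and natural killer cells (0.32) in anti-PD1 against isotype control, Wnt targets (0.42) in combination against isotype control, and type I interferon response (-0.39) and pigment genes (-0.12) in the interaction. The cause was not tested. Leaving out 1 library of the groups compared gave 7723 to 9169, 3976 to 4557, 6634 to 8364, 4575 to 4785, 5252 to 6330 and 4218 to 5142 genes, and leaving out 1 of another group gave up to 9449, 6028, 8605, 5357 and 6832 in the first 5. Of 3852 gene values 3759 kept direction and side of the threshold, 70 weakened, 10 strengthened, 11 moved and 2 turned. Of 2446 list medians 2196 kept both, 84 weakened, 47 strengthened, 112 moved and 7 turned. Replicate numbers do not pair the samples: over 5508 genes the deviations of 18 same-numbered pairs correlated at -0.105 to 0.194, 1 of them over 0.1, and 6 of 12 libraries were closest to their own number. The replicate block gave 8564, 5053, 7649, 5134, 6137 and 4778 genes.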

Other observations

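No test reported here was chosen after seeing the interaction values, apart from those over genes well above background, with background subtracted and without satellite-like genes.

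The interaction of the antibodies, where a negative value means less than the sum of the log2 effects of each, went different ways in the other lists. Ribosomal protein genes had a negative interaction in 20 of 20, median -0.93 (adjusted p = 2.46e-12, and adjusted p = 0.079 with an estimated correlation), with Rplp0 at -1.24 ± 0.0699. Mitochondrially encoded genes had a positive one in 11 of 13, median 1.15 (adjusted p = 1.21e-07, and adjusted p = 0.136 with an estimated correlation). Plasma cell genes were negative in 4 of 6, median -2.48 (adjusted p = 0.00259, and adjusted p = 0.102 with an estimated correlation), with Iglc2 at -4.37 (-5.60 without isotype control replicate 1). Monocyte genes were negative in 5 and positive in 1 of 6, median -1.67 (adjusted p = 0.0236, and adjusted p = 0.0945 with an estimated correlation). B7 ligands and Cd47 were negative in 4 of 9 (5 adjusted over the list alone), median -0.55 (adjusted p = 0.023, adjusted p = 0.0813 with an estimated correlation, and 0.0785 with background subtracted). Chemokine genes were negative in 6 of 16, median -0.83 (adjusted p = 0.0335, and adjusted p = 0.0942 with an estimated correlation), and lost the call without isotype control replicate 3 (-0.98, adjusted p = 0.053) or anti-B7-H3 replicate 1 (-0.73, adjusted p = 0.0559), and with background subtracted (-1.45, adjusted p = 0.318). Red blood cell genes were negative in 4 of 5, median -1.35 (adjusted p = 0.00921, and adjusted p = 0.0632 with an estimated correlation). They lost the call without anti-B7-H3 replicate 1, 2 or 3 (-1.26, -1.15 and -1.04, adjusted p = 0.0827, 0.103 and 0.0959) or combination replicate 1, 2 or 3 (-1.21, -1.07 and -1.16, adjusted p = 0.0951, 0.102 and 0.101). Hypoxia genes were negative in 9 and positive in 3 of 19, median -0.30 (adjusted p = 0.0335, and adjusted p = 0.303 with an estimated correlation), and lost the call without isotype control replicate 2 (-0.24, adjusted p = 0.0699) or anti-PD1 replicate 3 (-0.28, adjusted p = 0.0737), over genes well above background (-0.10, adjusted p = 0.605) and with background subtracted (-0.29, adjusted p = 0.646).

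Keratinocyte genes had a positive interaction in 6 of 7, fitted median 3.44 (adjusted p = 0.00639, and adjusted p = 0.0541 with an estimated correlation). It lost the call without isotype control replicate 1 (1.78, adjusted p = 0.0581) or anti-PD1 replicate 2 or 3 (1.42 and 1.48, adjusted p = 0.127 and 0.111), lost it with background subtracted (2.40, adjusted p = 0.318), and stood at 2.11, 1.88, 1.97 and 1.93 without isotype control replicate 2, isotype control replicate 3, anti-PD1 replicate 1 and combination replicate 3. Pigment genes were positive in 3 of 7, median 1.24 (adjusted p = 0.0335, and adjusted p = 0.0945 with an estimated correlation). They lost the call without isotype control replicate 1, 2 or 3 (1.04, 1.02 and 1.04, adjusted p = 0.0523, 0.0596 and 0.0655), anti-B7-H3 replicate 1 or 2 (1.0 and 1.25, adjusted p = 0.0684 and 0.051), anti-PD1 replicate 2 (1.03, adjusted p = 0.0597) or combination replicate 2 or 3 (1.23 and 1.27, adjusted p = 0.0928 and 0.0528). Proliferation genes were positive in 10 of 24 (median 0.37) and did not pass (adjusted p = 0.0884), but passed without isotype control replicate 2 (0.28, adjusted p = 0.0273) and over genes well above background (0.57, adjusted p = 8.56e-05) or with background subtracted (0.25, adjusted p = 0.000104), although Ccnb1 stood at 0.76. T cell (median 0.16, adjusted p = 0.97), B cell (median 0.04, mean -0.26, downward test, 0.709), natural killer cell (median -0.05, mean 0.28, upward test, 0.959), cytotoxic effector (0.44, 0.959), dendritic cell (-0.21, 0.17, and 0.0323 over genes well above background, or 0.0727 there with an estimated correlation) and Wnt target lists (0.00, 0.959) did not pass. Of single genes Ifi44 stood at 2.85 and Cmpk2 at 2.35, both not called with background subtracted (adjusted p = 1 and 0.412). Acta1 stood at 9.25 (10.65 without anti-B7-H3 replicate 2) and Hbb-bt at -4.59 (-3.91 and -8.80 without isotype control replicate 1 and 3, -3.96 without anti-B7-H3 replicate 1). Myh4, Xirp2, Socs7 and Ttll10 led the positive side and Lpin1, Ifi47 and Tnfsf13 the negative side, with no size given because each had 0 or 1 reads in a group. Of these, Socs7 was not called with a replicate block (adjusted p = 0.0549), nor Myh4 and Xirp2 with background subtracted (adjusted p = 1). Cd276 stood at -0.48 ± 0.21 and did not pass (adjusted p = 0.0639), but did without isotype control replicate 1 (-0.87, adjusted p = 0.0038), anti-B7-H3 replicate 1 (-0.56, 0.0454), anti-PD1 replicate 3 (-0.56, 0.0308) or combination replicate 2 (-0.57, 0.0402). Pdcd1 (0.81 ± 0.837, adjusted p = 0.476) and Cd274 (-0.55 ± 0.332, adjusted p = 0.198) did not pass.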
